A study of Homo sapiens with 11 samples.

How the data were processed

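RNA abundance was measured by sequencing of poly(A) RNA in 786-O cells, a human clear cell kidney carcinoma line without functional VHL, the gene for a ubiquitin ligase subunit that marks hypoxia-inducible factors for degradation. The 9 RNA libraries fell into 3 groups of 3 by their labels, namely cells with a scrambled siRNA, with siRNA 1 against SFMBT1 and with siRNA 2 against SFMBT1, which has another target sequence. The series also lists 2 chromatin immunoprecipitation samples, an SFMBT1 precipitate and its input, which were not analysed here.

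Per the submitters' processing notes, cutadapt, STAR, Salmon and DESeq2 were used with the human genome build hg19. Their versions and settings, the annotation and whether counting used strand are not given in the sources used here. The authors deposited 1 table of 27315 gene symbols with a variance-stabilised expression value per gene and library, which the deposited name calls VST expression and which is on a log2-like scale. Differences between groups on this scale understate the change of genes near the floor. Per the file headers, the same table gives the authors' DESeq2 log2 fold change of knockdown against scrambled libraries, and the authors' adjusted p-value of that comparison. Both siRNAs were combined there, and the design formula is not given in the sources used here.

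The deposited values ranged from a floor of 4.156 to 18.84, and 6634 genes lay at the floor in every library. Low values had no common step, so reads could not be recovered, the depth per library is unknown, and no interval from counting error can be given. The number of genes at the floor was used as the only hint of depth per library. Reads from near-identical genes can be assigned to another copy, which makes the metallothionein, histone, ribosomal protein and gamma-protocadherin genes uncertain, as well as NBL1, which overlaps a read-through gene with MINOS1. The ribosomal protein genes RPL7, RPS27 and RPS28, abundant in human cells, had means of 4.27, 4.67 and 4.95, near the floor. Without a statement on strand, genes that overlap an antisense gene are uncertain too.

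Genes entered the test if their mean over the 9 libraries was at least 1 log2 unit above the floor, which left 14276 genes. Of their symbols, 13373 are current in a gene table of the assembly GRCh38.p14, 629 are older names and 274 were not found there. That table was used for names and for the order of neighbouring genes only. Each gene was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group and no covariate, with an empirical Bayes variance that follows the mean (6 residual and 5.11 prior degrees of freedom). The contrasts were the mean of both siRNA groups minus scrambled, each siRNA minus scrambled, and siRNA 2 minus siRNA 1. All p-values were two-sided, and Benjamini-Hochberg adjustment ran over the 14276 genes, with calls at an adjusted p under 0.05. SFMBT1 and SPHK1 were also tested by exact permutation of the libraries. All changes are in log2 units, and an error after ± is the limma standard error unless SD is written.

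The groups, contrasts, thresholds, gene lists, rule for named genes and alternative settings, apart from those stated to be later, were chosen before the data were examined. The named genes were SFMBT1, SPHK1, the 12 largest rises and 12 largest falls for the mean of both siRNAs, and the 5 largest in each direction for the other contrasts. They had to pass the adjusted p, have no overlap between the libraries compared in that direction, and have a mean above the median of 8.92 of the genes tested. Up to 4 members per list were added by the smallest p for the mean of both siRNAs. A few genes that these rules pick are not reported here. Other members are named where 5 or fewer of a list moved against the rest or where a list differed between the siRNAs, and these were chosen after their values were seen.

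The 27 lists covered SFMBT1 partners and MBT-domain genes, sphingolipid metabolism, hypoxia-inducible factor targets, DNA replication, mitosis, p53 targets, epithelial genes, mesenchymal genes, collagen and extracellular matrix, and integrins and adhesion. Further lists held interferon response, NF-kB and cytokine, TGF-beta target, unfolded protein response, amino acid response, cholesterol synthesis, fatty acid and lipid storage, glycolysis, oxidative phosphorylation, ribosomal protein, replication-dependent histone, and autophagy and lysosome genes. The last lists held germline, kidney proximal tubule, microRNA machinery, growth factor and receptor, and blood and endothelial cell genes. The 26 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation, and with fry, which tests whether members move one way on balance and does not compare them with other genes. A call lost with an estimated correlation need not come from correlation between members. For NF-kB and cytokine genes the estimate was -0.031, under the preset. Yet the unadjusted camera p for the mean of both siRNAs rose from 0.0020 to 0.0135.

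The limma step was tested on simulated data with 14276 genes, each drawn on its own. In each simulation 67, 67 and 66 genes were changed by 0.5, 1 and 2 log2 units. For the mean of both siRNAs it recovered 58.2% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 log2 units, and called 0.0355% of unchanged genes. For siRNA 1 the shares were 32.8%, 95.5% and 100%, and for the difference between the siRNAs 25.4%, 98.5% and 100%. The adjusted p depends on how many genes change, and real genes vary together within groups. These shares therefore do not carry over to the real contrasts, where 6511 genes were called for the mean of both siRNAs. Overlap between the siRNAs was compared with 50 simulations of unchanged groups, in which all 9 libraries, the shared controls among them, were drawn anew gene by gene. Alternatives were other filters on low values, median centring and quantile normalisation, other variance models, the replicate number as a block, stricter thresholds, a fit of only the groups compared, the authors' own test, and leaving out each library. A search for matches to the siRNA seeds needs transcript sequences, and was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.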

Results

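Poly(A) RNA of 786-O cells was profiled in 9 libraries after transfection of a scrambled siRNA or of either of 2 siRNAs against SFMBT1, with 3 libraries in each group. SFMBT1 encodes a chromatin protein with MBT domains that binds histones and acts in repressive complexes, and the series concerns its part in kidney carcinoma cells that lack VHL. Expression is given as variance-stabilised values on a log2-like scale, with a floor of 4.156, and the sequencing depth is unknown. The median over the tested genes lay between 8.84 and 8.88 in the scrambled libraries and between 8.89 and 8.96 in the knockdown libraries. Genes at the floor numbered 9126, 9348 and 9151 in the scrambled libraries, 9802, 9807 and 9932 with siRNA 1, and 9867, 10027 and 9904 with siRNA 2, so that each knockdown library had more of them than each scrambled library. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

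The first comparison asked whether each siRNA lowered its target, and whether SPHK1, the gene for sphingosine kinase 1 that the study followed, changed with it. SFMBT1 fell with both siRNAs, to about 0.634 of the scrambled level if the values are read as log2. The scale is only log2-like, and the authors' log2 fold change of -0.84 is a larger fall. SFMBT1 read 7.65, 7.66 and 7.33 in the scrambled libraries, 6.94, 6.87 and 6.97 with siRNA 1, and 6.88, 6.64 and 7.04 with siRNA 2. Group means were 7.55 ± 0.19 for scrambled, 6.93 ± 0.05 for siRNA 1 and 6.85 ± 0.20 for siRNA 2 (SD, n = 3 each). SPHK1, whose product makes sphingosine-1-phosphate, fell as well, from 10.10 ± 0.12 to 9.65 ± 0.06 with siRNA 1 and 9.78 ± 0.15 with siRNA 2 (SD, n = 3 each).

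For SFMBT1 the change was -0.66 ± 0.12 for the mean of both siRNAs (limma, adjusted p = 8.03e-04), -0.62 ± 0.13 for siRNA 1 (adjusted p = 0.00361) and -0.70 ± 0.13 for siRNA 2 (adjusted p = 0.00168). The siRNAs differed by -0.07 ± 0.13 in SFMBT1, which did not pass (limma, adjusted p = 0.835). For SPHK1 the change was -0.39 ± 0.09 for the mean of both (limma, adjusted p = 0.00548), -0.45 ± 0.11 for siRNA 1 (adjusted p = 0.00612) and -0.32 ± 0.11 for siRNA 2 (adjusted p = 0.0325). The difference of 0.13 ± 0.11 between the siRNAs did not pass (limma, adjusted p = 0.570). Both genes were lower in 6 of 6 knockdown libraries than in any scrambled library, for a two-sided exact permutation p of 0.0119, the smallest that 84 splits allow. Such separation was common, as it held in either direction for 38.8% of the genes tested, and 45.6% were called for the mean of both. For either siRNA alone the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The authors' deposited table gives -0.84 for SFMBT1 (adjusted p = 7.7e-06) and -0.40 for SPHK1 (adjusted p = 0.00186). The SPHK1 call for siRNA 2 was lost without scrambled library 2 (-0.30, limma adjusted p = 0.0866), scrambled library 3 (-0.27, adjusted p = 0.118) or siRNA 2 library 3 (-0.23, adjusted p = 0.114).

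**Figure D1:**
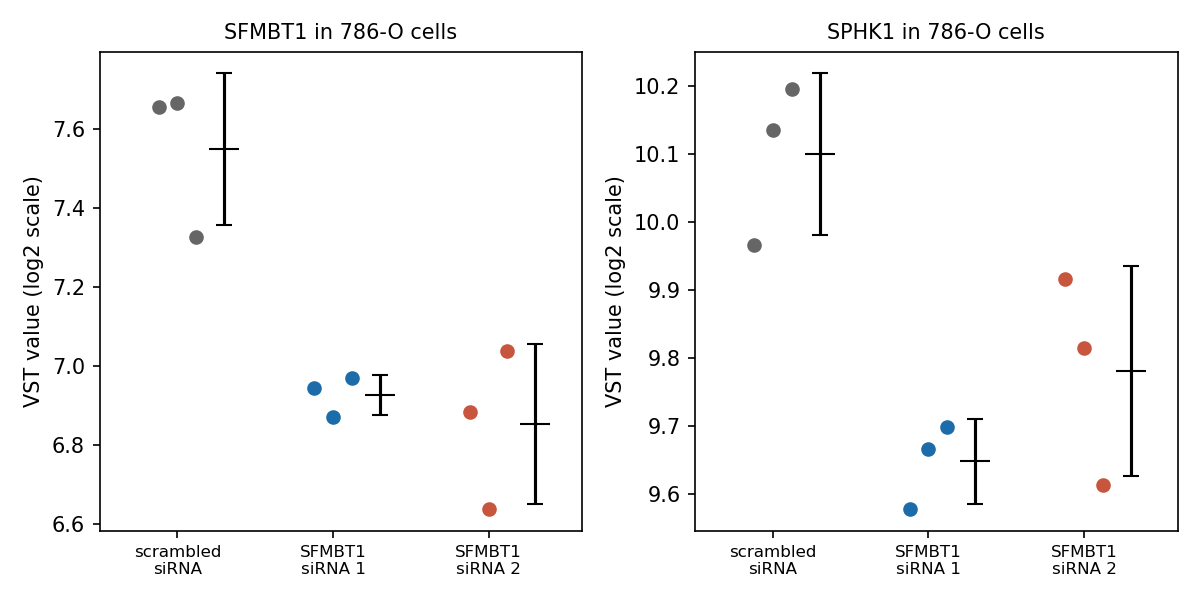
Variance-stabilised expression (log2 scale) of SFMBT1 and SPHK1 in each of 9 libraries of 786-O cells, with the group mean and SD (n = 3) beside the points, on axes that do not start at 0. All 6 knockdown libraries lie below the 3 scrambled libraries for both genes, with SFMBT1 means of 7.55, 6.93 and 6.85 and SPHK1 means of 10.10, 9.65 and 9.78.

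The mean of both siRNAs against scrambled asked which genes changed on average over the 2 siRNAs. A call there does not require a change with each siRNA. The largest rises among the genes named by size were those of ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 2.65 ± 0.12 (limma, adjusted p = 7.7e-08), and of the metallothionein gene MT1E by 2.43 ± 0.09 (adjusted p = 3.8e-08), over 6 knockdown and 3 scrambled libraries. Cell cycle genes made up much of the rest, with CDC6, which loads the replicative helicase, at 2.37 ± 0.09 and DTL, a substrate receptor that guards against re-replication, at 2.28 ± 0.09. The largest fall among them was that of MMP7, a matrix metalloproteinase, at -2.83 ± 0.09 (limma, adjusted p = 2.2e-08), to 0.140 of the scrambled level if the values are read as log2. RRAD, a Ras-related GTPase, changed by -2.27 ± 0.10 and LAMA5, a laminin chain of basement membranes, by -2.04 ± 0.10.

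Among the other named rises were MYBL2, a transcription factor of cycling cells, at 2.18 ± 0.12, the chromatin protein gene HMGB2 at 2.15 ± 0.10 and PTHLH, the parathyroid hormone-related protein, at 2.15 ± 0.11. TMEM97, a sterol-responsive membrane protein, rose by 2.14 ± 0.09 and HJURP, which deposits centromeric histone, by 2.10 ± 0.08. The metallothionein MT2A rose by 2.05 ± 0.14 and the flap endonuclease FEN1 by 2.05 ± 0.09. The other named falls were SEMA3A, a secreted guidance cue, at -1.80 ± 0.15, VASN, a TGF-beta binding protein, at -1.78 ± 0.11, and RAPGEF3, a cAMP-activated exchange factor, at -1.71 ± 0.12. BMF, a pro-apoptotic BH3-only protein, changed by -1.71 ± 0.13 and S1PR1, a sphingosine-1-phosphate receptor, by -1.68 ± 0.11. LRCH2 followed at -1.63 ± 0.20, FAM84B at -1.61 ± 0.13, CD74, the invariant chain of antigen presentation, at -1.59 ± 0.14, and the protocadherin PCDHGC3 at -1.52 ± 0.15.

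In all, 6511 of 14276 genes changed, 3313 upward and 3198 downward (limma, adjusted p under 0.05), and 547 and 358 of these by at least 1 log2 unit. With each library centred on its median, the split was 2669 upward and 3902 downward. The fit keeps the difference between the siRNAs out of the spread, so genes moved by 1 siRNA can be called. NBL1 was called (limma, adjusted p = 6.1e-05) at 0.35 with siRNA 1 and -2.30 with siRNA 2. The authors' adjusted p for NBL1, with both siRNAs combined, was 0.712. In turn, 4285 genes passed in the same direction with each siRNA. The knockdown libraries did not overlap the scrambled libraries in 38.8% of genes, where chance gives 2.38%. The authors' deposited table lists 6381 genes under an adjusted p of 0.05, 3200 higher and 3181 lower, of 17527 with an adjusted p. Of the tested genes, 5919 were called both here and in the authors' deposited table, all with the same sign, 592 here only and 67 in the authors' deposited table only. Across genes, which are not independent replicates, the fold changes in the authors' deposited table correlated with those given here at r = 0.962.

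Genes of DNA replication rose almost as a whole. Of 41 measured, 39 rose and 1 fell, also when adjusted over the list alone. The median was 1.55 (camera, adjusted p = 4.3e-26, and adjusted p = 0.0352 with an estimated correlation). CDC45, part of the replicative helicase, rose by 2.04 ± 0.08 and CLSPN, the checkpoint adaptor claspin, by 2.02 ± 0.08. The only fall was CCNE1, the G1/S cyclin E1, at -0.45 ± 0.09 (limma, adjusted p = 0.0022), and the polymerase subunit POLE2 stayed uncalled at 0.05 ± 0.10. All 41 mitosis genes rose, also when adjusted over the list alone. The median was 1.25 (camera, adjusted p = 3.7e-24, but adjusted p = 0.105 with an estimated correlation). NUSAP1, a spindle protein, rose by 1.75 ± 0.07, the kinase gene AURKB by 1.92 ± 0.09, the securin gene PTTG1 by 1.22 ± 0.07 and RACGAP1, which acts in cytokinesis, by 1.36 ± 0.08.

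Of 35 measured targets of hypoxia-inducible factors, 20 rose and 4 fell, and 22 and 4 when adjusted over the list alone. The median was 0.42 (camera, adjusted p = 1.0e-05, but adjusted p = 0.105 with an estimated correlation). Besides ANGPTL4, the carbonic anhydrase gene CA12 rose by 1.79 ± 0.08 and HILPDA, a lipid droplet protein, by 1.57 ± 0.08. The 4 that fell were CA9, another carbonic anhydrase and a classic hypoxia marker, at -1.40 ± 0.12 (authors' log2 fold change -2.75, with knockdown means near the floor), PFKFB3, which makes an activator of glycolysis, at -1.10 ± 0.07, the collagen crosslinker LOX at -0.63 ± 0.16 and the MYC antagonist MXI1 at -0.29 ± 0.10. Glycolysis genes, which overlap this list, had 8 rises and 2 falls among 21, and 11 and 3 when adjusted over the list alone. The median was 0.24 (camera, adjusted p = 0.0302, but adjusted p = 0.490 with an estimated correlation). ENO2 rose by 1.46 ± 0.11, ENO1 by 1.07 ± 0.08 and the glucose transporter gene SLC2A1 by 1.07 ± 0.08, while PFKFB3 and the phosphofructokinase gene PFKM, at -0.68 ± 0.08, fell.

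Cholesterol synthesis genes rose in 18 of 26 cases and fell in 2, also when adjusted over the list alone. The median was 0.51 (camera, adjusted p = 4.0e-04, but adjusted p = 0.105 with an estimated correlation). ACAT2 rose by 1.30 ± 0.08, FDPS by 1.09 ± 0.08, EBP by 1.08 ± 0.10 and IDI1 by 0.96 ± 0.11, all enzymes of the pathway or its precursors. The late enzymes LSS and TM7SF2 fell, at -0.41 ± 0.13 and -0.40 ± 0.12. Among 26 genes of fatty acids and lipid storage, 11 rose and 3 fell, and 12 and 3 when adjusted over the list alone. The median was 0.24 (camera, adjusted p = 0.0387, but adjusted p = 0.379 with an estimated correlation). The desaturase genes SCD and FADS1 rose by 0.96 ± 0.08 and 0.80 ± 0.08 and the lipid droplet coat gene PLIN2 by 0.42 ± 0.07. CPT1A, which acts in fatty acid oxidation and not in storage, rose by 1.03 ± 0.10, while the lipase gene PNPLA2 (-0.54 ± 0.13), DGAT2 (-0.41 ± 0.13, but -0.11 with siRNA 2 alone), which makes triglyceride, and PLIN3 (-0.32 ± 0.10) fell. Of 26 amino acid response genes 13 rose and 5 fell, and 14 and 5 when adjusted over the list alone. The median was 0.26 (camera, adjusted p = 0.0348, but adjusted p = 0.379 with an estimated correlation). The transporter genes SLC1A4 and SLC7A1 rose by 1.83 ± 0.11 and 0.93 ± 0.07 and the stress pseudokinase gene TRIB3 by 0.87 ± 0.08, while NUPR1 (-1.20 ± 0.12), ATF5 (-0.79 ± 0.15), SESN2 (-0.73 ± 0.13), SLC7A11 (-0.72 ± 0.21) and CTH (-0.30 ± 0.09) fell. Without scrambled library 1 the calls of the glycolysis, amino acid and fatty acid lists were lost (camera, adjusted p = 0.0601, 0.0601 and 0.0741), and that of the fatty acid list also without scrambled library 3 (adjusted p = 0.0583), with quantile normalisation (0.0673) or with the filter at 2 log2 units above the floor (0.0662).

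Growth factor and receptor genes rose in 15 of 30 cases and fell in 2, also when adjusted over the list alone. The median was 0.30 (camera, adjusted p = 0.00500, but adjusted p = 0.117 with an estimated correlation). The members with the smallest p were MYC at 1.25 ± 0.10, FOSL1 at 1.89 ± 0.16 and ETV4 at 1.69 ± 0.16, which are transcription factors downstream of growth signals, and the ligand gene TGFA at 1.05 ± 0.09. ETV4 lay near the floor in scrambled cells (mean 4.80), where this scale understates change, and the authors' log2 fold change was 4.02. The ligand gene HBEGF (-0.56 ± 0.09) and the receptor gene PDGFRB (-0.61 ± 0.14) fell. Of 26 NF-kB and cytokine genes 14 rose and 4 fell, also when adjusted over the list alone. The median was 0.37 (camera, adjusted p = 0.00649, but adjusted p = 0.105 with an estimated correlation). CSF2, a myeloid growth factor gene, rose by 2.35 ± 0.12, the chemokine gene CCL2 by 1.31 ± 0.10, IL6 by 1.20 ± 0.07 and the kinase gene MAP3K8 by 1.03 ± 0.08, and TNFAIP2 (-0.72 ± 0.09), CXCL5 (-0.65 ± 0.24), IL1B (-0.62 ± 0.11) and BIRC3 (-0.49 ± 0.10) fell, BIRC3 with siRNA 1 only. The rise of CCL2 came from siRNA 2 (0.21 with siRNA 1, limma, adjusted p = 0.18, and 2.41 with siRNA 2). With siRNA 1 alone this list was not called (camera, adjusted p = 0.380).

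Among genes that fell as lists, those of collagen and extracellular matrix had 19 falls and 2 rises among 30 measured, also when adjusted over the list alone. The median was -0.48 (camera, adjusted p = 1.0e-04, but adjusted p = 0.105 with an estimated correlation). COL5A2 fell by 1.66 ± 0.10, the metalloproteinase inhibitor gene TIMP2 by 1.43 ± 0.08 and COL18A1 by 1.01 ± 0.10, whereas the laminin chain gene LAMC1 rose by 0.65 ± 0.08 and the collagenase gene MMP1 by 0.40 ± 0.12. The rise of MMP1 came from siRNA 2 alone (0.02 with siRNA 1 and 0.78 with siRNA 2, difference 0.76, limma, adjusted p = 0.0110). Epithelial genes fell in 13 of 22 cases and rose in 3, and in 13 and 4 when adjusted over the list alone. The median was -0.52 (camera, adjusted p = 0.0109, but adjusted p = 0.270 with an estimated correlation). The junction gene JUP fell by 1.57 ± 0.11 and the mucin gene MUC1 by 1.42 ± 0.13, while the tight junction gene CLDN1 rose by 0.96 ± 0.11 and the splicing factor gene ESRP2 by 0.30 ± 0.10. Of 12 measured genes of the kidney proximal tubule 7 fell and 0 rose, also when adjusted over the list alone. The median was -0.42 (camera, adjusted p = 0.00402, but adjusted p = 0.250 with an estimated correlation). The endocytic receptor gene CUBN fell by 1.53 ± 0.12, the dicarboxylate transporter gene SLC13A3 by 0.90 ± 0.10 and GGT1 by 0.55 ± 0.10. Interferon response genes fell in 13 of 33 cases and rose in 3, and in 15 and 3 when adjusted over the list alone. The median was -0.29 (camera, adjusted p = 0.0109, but adjusted p = 0.490 with an estimated correlation). IFI44L fell by 1.48 ± 0.10, IFIT2 by 1.04 ± 0.11 and HERC6 by 1.01 ± 0.11, while OAS3, a sensor of double-stranded RNA, rose by 0.85 ± 0.11, XAF1 by 0.37 ± 0.12 and DTX3L by 0.26 ± 0.08. In total 13 of 26 lists were called, 9 upward and 4 downward. Only the DNA replication list kept its call with an estimated correlation, and fry, which sets no list against other genes, called 17.

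**Figure D2:**
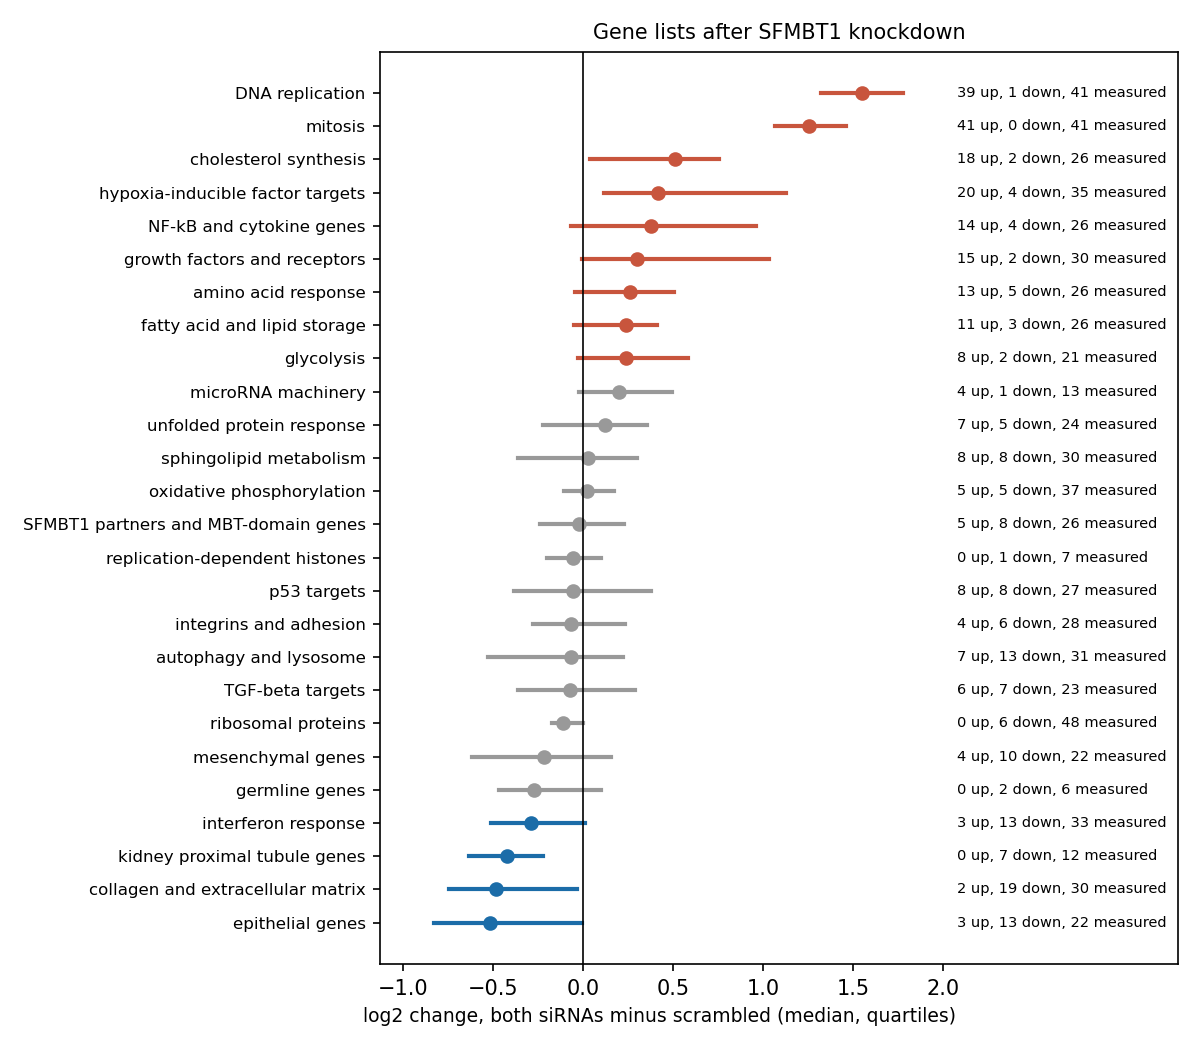
Median (point) and quartiles (line) of the log2 change, both siRNAs minus scrambled, for each of 26 gene lists fixed in advance, with the number of members that rose or fell at an adjusted p under 0.05. Red lists were called upward and blue lists downward by camera with its preset correlation, and grey lists were not called; DNA replication (median 1.55) and mitosis (1.25) lie apart from the rest.

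The other 13 tested lists held single genes that changed without a call for the list (camera). Of 26 SFMBT1 partners and MBT-domain genes 5 rose and 8 fell, also when adjusted over the list alone (median -0.02, adjusted p = 0.786). ZMYM3 lay at -0.74 ± 0.10, PHF21A at -0.54 ± 0.10, YY1 at 0.62 ± 0.10 and L3MBTL2 at 0.36 ± 0.08. Sphingolipid metabolism, the pathway of SPHK1, had 8 rises and 8 falls among 30, also when adjusted over the list alone (adjusted p = 0.938). Its median was 0.02, its mean -0.03 and its test direction downward, and the median changed sign with median centring. The receptor gene S1PR3 rose by 1.30 ± 0.10 where S1PR1 fell, the lysosomal sphingomyelinase gene SMPD1 fell by 1.06 ± 0.09 and SGPL1, which degrades sphingosine-1-phosphate, rose by 0.49 ± 0.07. Of 27 p53 targets 8 rose and 8 fell, and 10 and 8 when adjusted over the list alone (median -0.06, mean 0.02 and direction upward, adjusted p = 0.998). RPS27L lay at 1.49 ± 0.09, DDB2 at 1.28 ± 0.11, GDF15 at -1.32 ± 0.10 and PLK2 at -0.52 ± 0.08. Mesenchymal genes had 4 rises and 10 falls among 22, and 5 and 10 when adjusted over the list alone (median -0.21, adjusted p = 0.195). The hyaluronan receptor gene CD44 lay at 1.44 ± 0.08, SPARC at -1.18 ± 0.09 and LOXL2 at -0.93 ± 0.11. Integrins and adhesion had 4 rises and 6 falls among 28, also when adjusted over the list alone (median -0.06, adjusted p = 0.569). ITGA6 lay at 1.34 ± 0.17, CAV1 at 1.26 ± 0.18, ITGA1 at -1.10 ± 0.15 and ITGB4 at -0.78 ± 0.15. TGF-beta targets had 6 rises and 7 falls among 23, and 7 and 8 when adjusted over the list alone (median -0.07, mean 0.04 and direction downward, adjusted p = 0.843). ID3 lay at -0.99 ± 0.11, ID1 at -0.78 ± 0.08 and BHLHE40 at 0.71 ± 0.08.

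Unfolded protein response genes had 7 rises and 5 falls among 24, and 8 and 5 when adjusted over the list alone (median 0.12, camera adjusted p = 0.295). MANF lay at 1.44 ± 0.07, the chaperone gene HSPA5 at 0.84 ± 0.09 and XBP1 at 0.54 ± 0.08. Autophagy and lysosome genes had 7 rises and 13 falls among 31, and 8 and 13 when adjusted over the list alone (median -0.07, camera adjusted p = 0.135, and 0.0433 with quantile normalisation). The sialidase gene NEU1 lay at -1.30 ± 0.09, GABARAPL2 at -0.81 ± 0.09, the autophagy receptor gene SQSTM1 at -0.79 ± 0.08 and GLA at 0.73 ± 0.09. MicroRNA machinery genes had 4 rises and 1 fall among 13, and 6 and 1 when adjusted over the list alone (median 0.20, camera adjusted p = 0.133). DGCR8 lay at 1.05 ± 0.09, DROSHA at 0.99 ± 0.09, AGO2 at 0.50 ± 0.12 and TNRC6B at -0.23 ± 0.07. Oxidative phosphorylation genes had 5 rises and 5 falls among 37, and 5 and 4 when adjusted over the list alone (median 0.02, mean -0.001 and direction upward, camera adjusted p = 0.996), and the median changed sign with median centring. SDHC fell by 0.46 ± 0.10, while NDUFA9 rose by 0.51 ± 0.11. Of 48 ribosomal protein genes 6 fell, and 3 when adjusted over the list alone (median -0.11, camera adjusted p = 0.0764, and adjusted p = 0.763 with an estimated correlation of 0.448). RPS9 lay at -0.36 ± 0.07 and RPL30 at -0.31 ± 0.08. This list was called downward with median centring (camera, adjusted p = 0.0478), quantile normalisation (0.0414), a stricter filter (0.0418), and without scrambled library 1 (0.0371), scrambled library 3 (0.0403) or siRNA 1 library 3 (0.0157). Only 7 of 24 listed replication-dependent histone genes passed the filter in this poly(A) RNA. Of these HIST1H2AC fell by 0.71 ± 0.10, the only call, also when adjusted over the list alone (median -0.06, camera adjusted p = 0.697). Of 6 germline genes STAG3 fell by 0.85 ± 0.14 and SYCP2 by 0.52 ± 0.12, also when adjusted over the list alone (median -0.27, camera adjusted p = 0.359). Blood and endothelial markers had only 2 measured members, which is too few for a list test, and CD68 fell by 0.58 ± 0.12 (limma, adjusted p = 0.0021) while CSF1R lay at -0.23 ± 0.11 (adjusted p = 0.10).

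Each siRNA alone was compared with scrambled to see whether reagents of different sequence moved the same genes. Among genes that met the rule for naming by size, the rises with siRNA 1 included those of ANGPTL4 (3.09 ± 0.14), CDC6 (2.45 ± 0.10), MT1E (2.41 ± 0.10) and DTL (2.27 ± 0.10), over 3 against 3 libraries. The largest falls were those of RRAD (-3.14 ± 0.11), MMP7 (-2.66 ± 0.11), LAMA5 (-2.47 ± 0.11), SEMA3A (-1.91 ± 0.17) and PCDHGC3 (-1.90 ± 0.17). With siRNA 2, MT1E (2.45 ± 0.10), PTHLH (2.30 ± 0.12), CDC6 (2.30 ± 0.10), DTL (2.29 ± 0.10) and HMGB2 (2.24 ± 0.11) rose most by that rule, and MMP7 (-3.00 ± 0.11) fell most. It was followed by NBL1, a BMP antagonist, at -2.30 ± 0.14, the Golgi protein gene TGOLN2 at -2.03 ± 0.12, CHPF, which acts in chondroitin synthesis, at -2.00 ± 0.16, and the mitochondrial kinase gene PINK1 at -1.85 ± 0.12. All of these calls held without each library in turn (limma).

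With siRNA 1, 5543 genes changed, 2868 upward and 2675 downward (limma), and 2259 and 3268 with median centring. With siRNA 2, 5944 changed, 3034 upward and 2910 downward, and 2460 and 3477 with median centring. Libraries did not overlap in 50.6% of genes for siRNA 1 and 53.1% for siRNA 2, where chance gives 10%. DNA replication (medians 1.58 and 1.43) and mitosis (1.31 and 1.26) rose with either siRNA, with 39 of 41 and 41 of 41 members higher in each case, also when adjusted over the list alone. Hypoxia-inducible factor targets had 21 rises and 3 falls among 35 with siRNA 1 (camera, adjusted p = 5.8e-06) and 19 and 4 with siRNA 2 (adjusted p = 3.5e-05), and the same counts when adjusted over the list alone, but adjusted p = 0.109 and 0.118 with an estimated correlation. Cholesterol synthesis had 17 rises and 1 fall among 26 with siRNA 1 and 18 and 2 with siRNA 2, and growth factors 15 and 2 and then 13 and 3 among 30, also when adjusted over the list alone. Matrix genes had 1 rise and 19 falls among 30 with siRNA 1 and 2 and 16 with siRNA 2 (2 and 17 when adjusted over the list alone), and tubule genes 8 falls among 12 (9 when adjusted over the list alone) and then 6 falls and 1 rise. Epithelial (camera, adjusted p = 0.00107), glycolysis (0.00729), amino acid (0.0146) and fatty acid lists (0.0146) were called for siRNA 1, and the interferon list for siRNA 2 (0.00174), none with an estimated correlation (adjusted p = 0.147, 0.383, 0.295, 0.295 and 0.505). The amino acid and fatty acid lists did not differ between the siRNAs past the threshold (camera, adjusted p = 0.303 and 0.137). Camera called 11 lists for siRNA 1 (8 upward) and 9 for siRNA 2 (6 upward), of which DNA replication kept its call with an estimated correlation for both (adjusted p = 0.0271 and 0.0351) and NF-kB for siRNA 2 (adjusted p = 0.0351). The others reached adjusted p = 0.109 to 0.383 with an estimated correlation for siRNA 1 and adjusted p = 0.0935 to 0.505 for siRNA 2, and fry called 17 and 19 lists. The tubule call for siRNA 2 (camera, adjusted p = 0.0462) was lost without scrambled library 2 (0.0651), siRNA 1 library 2 (0.0506) or siRNA 2 library 3 (0.114), and with median centring (0.0585) or quantile normalisation (0.0592), and its growth factor call was lost with a stricter filter (0.0726).

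The siRNAs changed 4285 genes the same way, 2293 upward and 1992 downward, and 19 genes in opposite ways. With all 9 libraries drawn anew, unchanged groups that shared a simulated control gave 0.04 genes on average over 50 simulations. Each gene was drawn on its own, so the simulations hold no offset of the control common to many genes. Independent lists of the same sizes would share 1155, 610 upward and 545 downward. Across genes, which are not independent replicates, the changes by the siRNAs correlated at r = 0.890, against 0.501 in the simulations, and 84.1% of genes had the same sign, against 66.6%. Their covariance was 0.244, against 0.0105 in the simulations, a difference of 0.233. The 3 scrambled libraries cannot be split into parts of at least 2 each, so part of the excess may come from the shared controls.

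**Figure D3:**
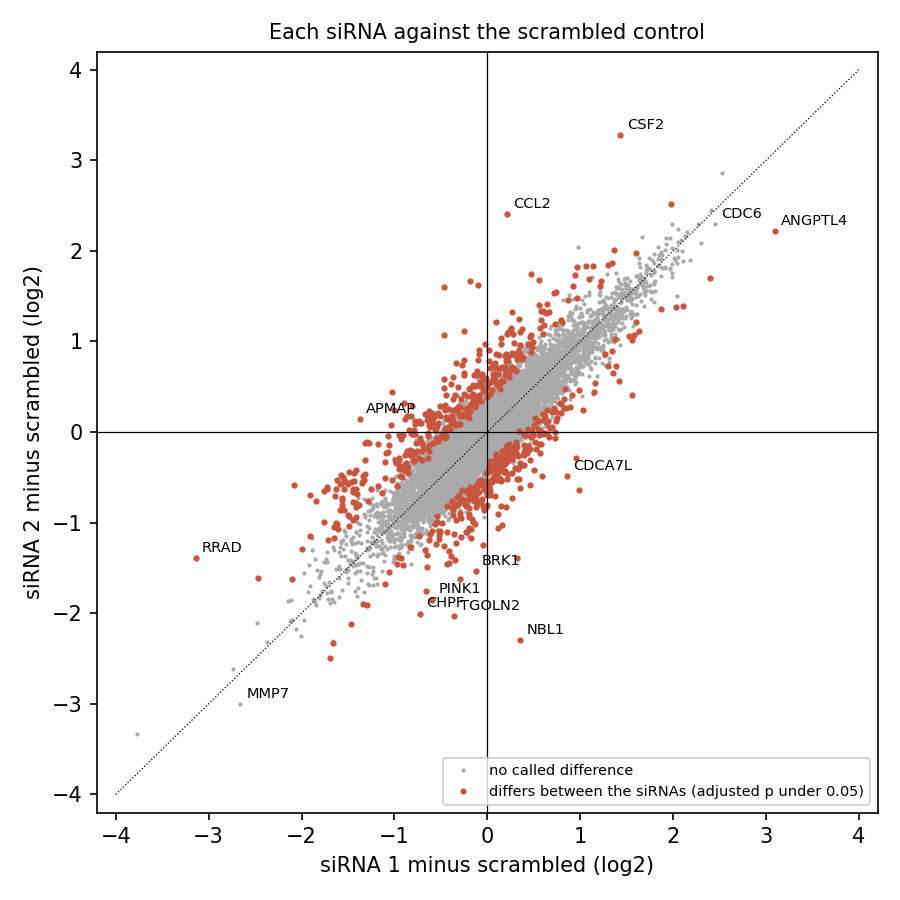
Log2 change with siRNA 2 against log2 change with siRNA 1, each minus the same 3 scrambled libraries, for the 14276 genes tested. Red points are the 677 genes that differed between the siRNAs at an adjusted p under 0.05, such as CCL2 and NBL1, and the dotted line marks equal change.

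The direct test of siRNA 2 against siRNA 1, which does not involve the scrambled group means, asked where the reagents differ. Genes of NF-kB and cytokines were higher with siRNA 2, with 12 higher and 1 lower of 26, and 15 and 1 when adjusted over the list alone. CCL2 stood 2.19 ± 0.12 higher with siRNA 2, CCL20 1.86 ± 0.21 and CSF2 1.84 ± 0.14 (3 against 3 libraries). RRAD (1.74 ± 0.11), APMAP (1.51 ± 0.09), SPNS2, a sphingosine-1-phosphate exporter (1.46 ± 0.13), FXYD2, a regulator of the sodium pump (1.21 ± 0.13), and CRABP2, a retinoic acid binding protein (1.11 ± 0.20), were the genes named by size that were higher with siRNA 2. NBL1 (-2.65 ± 0.14), TGOLN2 (-1.66 ± 0.12), the actin regulator gene BRK1 (-1.41 ± 0.09), CDCA7L (-1.35 ± 0.09) and TM2D1 (-1.33 ± 0.15) were lower.

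The genes that differ between the siRNAs numbered 677, 364 higher and 313 lower with siRNA 2 (limma, adjusted p under 0.05), and 42 and 22 of them by at least 1 log2 unit. Libraries of the siRNAs did not overlap in 23.3% of genes, where chance gives 10%. The count fell to 275 without siRNA 1 library 1, 384 without siRNA 1 library 2 and 296 without siRNA 2 library 1. It was 313 with the replicate number as a block and 331 from the 6 libraries of the groups compared, and rose to 1484 without 3 libraries at one end of the within-group axis. RRAD fell with both siRNAs (-3.14 with siRNA 1 and -1.39 with siRNA 2), as did CRABP2 (-1.76 and -0.65). CDCA7L rose with siRNA 1 (0.86) and fell with siRNA 2 (-0.49), and SPNS2 fell with siRNA 1 (-1.02) and rose with siRNA 2 (0.44). APMAP (-1.37 and 0.14) and FXYD2 (-0.90 and 0.32) fell with siRNA 1 and did not pass for siRNA 2 (limma, adjusted p = 0.21 and 0.07). NBL1 (0.35 and -2.30), BRK1 (-0.12 and -1.54) and TM2D1 (-0.30 and -1.63) fell with siRNA 2 and did not pass for siRNA 1 (limma, adjusted p = 0.06, 0.31 and 0.14). TGOLN2 fell with both (-0.36 and -2.03).

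For NF-kB and cytokine genes the median difference between the siRNAs was 0.42 (camera, adjusted p = 6.6e-12, and adjusted p = 0.00465 with an estimated correlation). With siRNA 1 alone 7 of the 26 rose and 4 fell, 7 and 5 when adjusted over the list alone (median 0.06, camera adjusted p = 0.380), and with siRNA 2 alone 16 rose and 2 fell, also when adjusted over the list alone (median 0.61, camera adjusted p = 7.6e-05, and adjusted p = 0.0351 with an estimated correlation). CCL2 changed by 0.21 with siRNA 1 (limma, adjusted p = 0.18) and by 2.41 with siRNA 2, and CSF2 rose by 1.43 and 3.28. TNFAIP3, an inhibitor of this pathway, lay at -0.09 and 0.91 and stood 0.99 ± 0.09 higher with siRNA 2 (limma, adjusted p = 2.3e-04), and BIRC3, at -0.95 and -0.04, stood 0.92 ± 0.11 higher. IL6 went the other way, with 1.38 for siRNA 1 and 1.03 for siRNA 2, a difference of -0.35 ± 0.08 (limma, adjusted p = 0.0353) whose call was lost without any of 8 libraries (adjusted p up to 0.127).

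**Figure D4:**
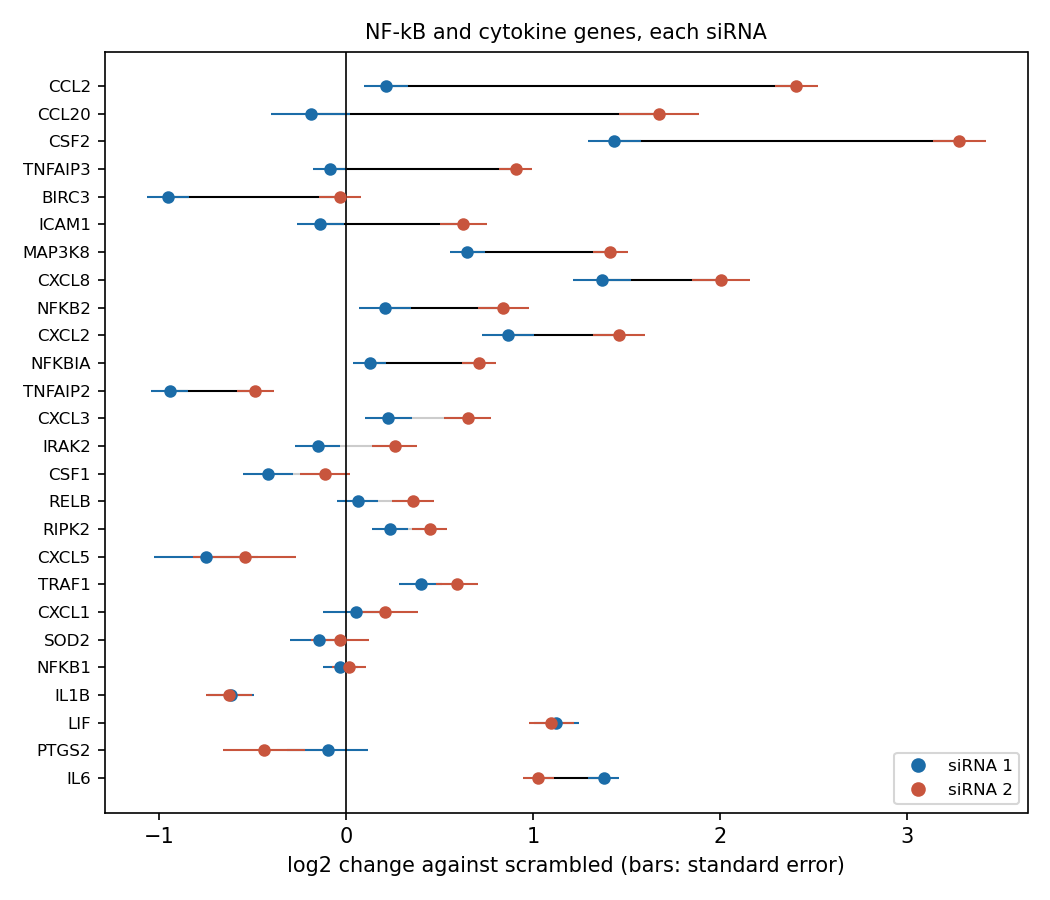
Log2 change against scrambled with its standard error for each of 26 measured NF-kB and cytokine genes, with siRNA 1 in blue and siRNA 2 in red, ordered by their difference. Black lines join the siRNAs where the difference passed the test, with CCL2 at 0.21 and 2.41 and CSF2 at 1.43 and 3.28, and grey lines where it did not.

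Camera called 8 further lists for the difference, none with an estimated correlation. Of 24 replication-dependent histone genes listed, only 7 passed the filter in this poly(A) RNA. Some lay near the floor, such as HIST1H2BC at 5.19 to 5.82 in the knockdown libraries. The histone genes measured were higher with siRNA 2 (median 0.30, adjusted p = 2.0e-04, and adjusted p = 0.0898 with an estimated correlation), with 3 of 7 called, also when adjusted over the list alone. So were epithelial genes (median 0.18, adjusted p = 0.00143, and adjusted p = 0.325 with an estimated correlation), proximal tubule genes (0.23, adjusted p = 0.00949, and 0.325 with an estimated correlation) and extracellular matrix genes (0.16, adjusted p = 0.0224, and 0.325 with an estimated correlation). DNA replication genes (median -0.11, adjusted p = 6.8e-04, and adjusted p = 0.325 with an estimated correlation) and interferon response genes (-0.25, adjusted p = 6.9e-04, and 0.379 with an estimated correlation) were lower, the latter with 3 of 33 called and 3 higher and 10 lower when adjusted over the list alone. Glycolysis (-0.078, adjusted p = 0.0224, and adjusted p = 0.511 with an estimated correlation) and mesenchymal genes (-0.078, adjusted p = 0.0415, and 0.345 with an estimated correlation) were lower too. Higher and lower members numbered 2 and 0 of 22 epithelial, 2 and 0 of 12 tubule, 2 and 1 of 30 matrix, 0 and 3 of 41 replication, 0 and 0 of 21 glycolysis and 0 and 5 of 22 mesenchymal genes (limma). These counts were 5 and 0, 3 and 0, 3 and 1, 0 and 5, 0 and 3, and 0 and 6 when adjusted over the list alone. Without siRNA 2 library 2 the tubule (camera, adjusted p = 0.0624) and matrix calls (0.179) were lost. The matrix call was also lost with a stricter filter (0.0679) and the glycolysis call without siRNA 1 library 3 (0.0941) or siRNA 2 library 3 (0.0591). Both were lost without 3 libraries at one end of the within-group axis (0.120 and 0.0641), a setting chosen after the data were seen. The histone list had too few genes to be tested under the stricter filter. The mesenchymal call was lost without siRNA 1 library 2 (0.0752), siRNA 2 library 1 (0.0554) or siRNA 2 library 3 (0.0963).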

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

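In this part, the tests of replicate batches and of library depth were chosen only after the results were seen, as was the share among differences of at least 1 log2 unit.

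The siRNAs share a target but differed in 30 of 130 named genes by the direct test of siRNA 2 minus siRNA 1 (limma, adjusted p under 0.05, 3 against 3 libraries), which is why these are listed here. Some were named for the size of this difference or of the change with 1 siRNA, so the naming rule raises the share. Over all genes tested 677 of 14276 differed (4.74%). Values that follow are log2 differences, positive where siRNA 2 was higher. Among genes led by the size of change, RRAD (1.74), APMAP (1.51), SPNS2 (1.46), FXYD2 (1.21), CRABP2 (1.11), LAMA5 (0.86) and PCDHGC3 (0.76) were higher. NBL1 (-2.65), TGOLN2 (-1.66), BRK1 (-1.41), CDCA7L (-1.35), TM2D1 (-1.33), CHPF (-1.28), PINK1 (-1.25) and ANGPTL4 (-0.87) were lower. Among list members, CCL2 (2.19), CSF2 (1.84), GABARAPL2 (1.00), HIST1H2BD (1.00), ITGA6 (0.79), MAP3K8 (0.76), CLDN1 (0.75), SLC13A3 (0.47), CA12 (0.38), PLIN2 (0.37) and SGPL1 (0.36) were higher, and LOXL2 (-1.03), SMPD1 (-0.44), PLK2 (-0.39) and IL6 (-0.35) were lower. Without each library in turn 21 of the 30 stayed past the threshold and 9 did not, namely PCDHGC3, which was lost without scrambled library 3, siRNA 1 library 1 or siRNA 2 libraries 1 or 2 (limma, adjusted p up to 0.127), and SMPD1, SGPL1, CA12, PLK2, ITGA6, IL6, PLIN2 and SLC13A3. Each of these 8 was lost without any of 6 to 8 libraries, siRNA 1 library 1 and siRNA 2 library 1 among them (limma, adjusted p up to 0.172).

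For the same contrast, camera at the preset correlation called 9 lists, of which only NF-kB and cytokine genes kept the call with an estimated correlation (adjusted p = 0.00465, the others 0.0898 to 0.511). Their median differences were 0.42 for NF-kB and cytokine genes, 0.30 for replication-dependent histones, 0.23 for proximal tubule genes, 0.18 for epithelial genes, 0.16 for extracellular matrix, -0.25 for interferon response, -0.11 for DNA replication, -0.078 for glycolysis and -0.078 for mesenchymal genes.

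The difference between the siRNAs in 677 genes was weighed against knockdown of unequal strength and against repression of other transcripts by 1 siRNA. Unequal strength needs differences that mostly share, or mostly oppose, the sign of the mean change, and 55.2% shared it, with SFMBT1 itself at -0.07 ± 0.13 between the siRNAs, which argues against it as the whole cause. Off-target repression would make the siRNA with the larger change lower the gene, which held in 59.4% of the 677 genes (196 of 303 for siRNA 1 and 206 of 374 for siRNA 2), between the 50% and 60% set as bounds, and in 44 of the 64 differences of at least 1 log2 unit, a share above 60%. It cannot be told apart from other differences between the reagents, because the share over all 677 genes, for which the bounds were set, decides neither way and seed matches were not searched, and it may account for strong falls with 1 siRNA such as that of NBL1. The 10 splits of the 6 libraries are too few for a share under 0.05, with 677 genes in the real split and 810 in the highest other.

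The split with 810 genes set siRNA 1 library 3 and siRNA 2 libraries 1 and 2 against the others, along an axis that the groups share. This axis took 65.6% of the variance within groups, against 10.8% for the next, with scrambled library 2 (-0.24), siRNA 1 library 3 (-0.54) and siRNA 2 library 2 (-0.49) at one end, together with NPIPB3, NPIPB5 and PPDPF, and TMED7, PARD6B and LYPLA1 at the other. The highest scores of the groups were 0.22 for scrambled library 1, 0.35 for siRNA 1 library 2 and 0.44 for siRNA 2 library 3. Batches that follow the replicate numbers are argued against as the source of this axis, since only 3 of 9 same-numbered pairs correlated above 0.1 and the lowest reached -0.73. A smaller batch by number is not excluded. The axis score went with the number of genes at the floor, both as deviations from group means (Pearson r = -0.788, two-sided exact permutation p = 0.0278, Spearman rho = -0.467, exact p = 0.222, 1 relation tested), and r was -0.633 without the 2 farthest libraries, so depth or RNA quality may be a source, although the rank correlation did not pass. No biological explanation was tested, as no label divides the libraries this way.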

How the results depend on the processing

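The setting without 3 libraries at one end of the axis within groups was chosen only after the data were seen. Of the values that answer a comparison, 200 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 16 moved further and 4 lost a call; none reversed. Of the values of named genes, 2247 kept both, 16 lost and 16 gained a call. SFMBT1 passed for each siRNA under every setting run. The count of genes that differ between the siRNAs was 313 with the replicate number as a block, 331 from the 6 libraries of the groups compared, 1484 without the 3 libraries, and 275 to 770 when 1 library was left out. The 3 libraries were the negative end of the axis, each with the most extreme score of its group. The margin was small for scrambled library 2 (-0.24, against 0.22 for library 1). It was small too for siRNA 2 library 2 (-0.49, against 0.44 for library 3). Leaving out the 3 libraries lowers the spread within groups by construction. Calls for the mean of both siRNAs rose there too, to 3828 upward and 3558 downward. The 1484 can thus not be read as a truer count, and other sources of the rise were not tested. For the genes changed by both siRNAs on average, leaving out 1 library gave 5119 to 6948.

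A change of at least 1 log2 unit, by construction, left 905 genes changed by both siRNAs on average, 938 genes changed by siRNA 1, 957 genes changed by siRNA 2, 64 genes that differ between the siRNAs and 666 genes changed the same way by each siRNA. An adjusted p under 0.01 left 3585, 3939, 231 and 2733 in the last 4 of these. With an estimated correlation 1 list, DNA replication, was called for the mean of both. SPHK1 with siRNA 2 lay at -0.23 to -0.39 when 1 library was left out, and its call ended without scrambled library 2 or 3 or siRNA 2 library 3.

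With the replicate number as a block, SPHK1 with siRNA 2 stood at -0.32 (limma, adjusted p = 0.0700, against 0.0325 without the block), and 5846 genes changed by both siRNAs on average were called. The main axis within groups does not follow the numbers: 3 of 9 same-numbered pairs correlated above 0.1, and 1 of 9 libraries correlated best with its own number. As that axis took 65.6% of the variance within groups, it could hide a smaller batch by number. Count-based tools, other pseudocounts and the seed search were not run, since the values are not counts, need no pseudocount, and come without transcript sequences. Depth is unknown, so it cannot be said which low genes it hides.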

Other observations

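In this part, the tests of gene families, of mislabelled libraries and of the state of the scrambled cells were chosen only after the results were seen, as were the genes named.

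Families of genes with a shared symbol stem moved together outside the fixed lists. Of 444 families with at least 5 measured members, 20 passed camera at the preset correlation and 0 with an estimated correlation, and the directions given here held under both scalings. Symbols with the stem NUP, mostly nucleoporins of the nuclear pore but also the antisense NUP50-AS1 and NUP62CL, rose in 20 of 22 cases (median 0.68, camera adjusted p = 6.0e-08, but adjusted p = 0.653 with an estimated correlation), with NUP205 at 1.33 and NUP85 at 1.18. All 8 HAUS genes, of the augmin complex that branches spindle microtubules, rose (median 0.99, camera adjusted p = 6.9e-04, but adjusted p = 0.653 with an estimated correlation), with HAUS8 at 1.73. Metallothioneins, which bind zinc and copper, rose in 4 of 5 cases (median 1.77, camera adjusted p = 0.00615, but adjusted p = 0.808 with an estimated correlation), with MT1X at 1.77 and MT1F at 1.55, and MT1L not called at 0.05. All 12 gamma-protocadherins of the A group fell, more with siRNA 1 (-1.33 to -1.72) than with siRNA 2 (-0.45 to -0.75), and each differed between the siRNAs (0.78 to 1.11, limma, adjusted p up to 0.0130). For their mean change over both siRNAs camera gave a call (median -1.05, camera adjusted p = 1.4e-06, but adjusted p = 0.808 with an estimated correlation). They share constant exons, so that their values are not independent. Symbols with the stem HOXA, 2 antisense and 1 readthrough transcript among them, fell in 8 of 14 cases (median -0.31, camera adjusted p = 0.0162, but adjusted p = 0.693 with an estimated correlation), with HOXA5 at -1.26, HOXA10 at -1.12 and HOXA9 at -0.85. The kidney cadherin genes CDH16 and CDH6 fell by 1.45 and 0.90, CDH16 more with siRNA 1 (difference 0.52, limma, adjusted p = 0.0435), and MMP13 fell by 3.55.

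EPAS1, the gene for HIF-2 alpha, the dominant hypoxia-inducible factor of this cell line, rose by 1.37 (1.63 with siRNA 1 and 1.12 with siRNA 2), and HIF1A by 0.71 (0.44 and 0.98). The difference of -0.51 in EPAS1 between the siRNAs (limma, adjusted p = 0.0169) was lost without siRNA 1 libraries 1 or 2 or siRNA 2 libraries 1 or 3 (adjusted p up to 0.0899). HIF1A differed the other way, by 0.54 (limma, adjusted p = 0.0103), which was lost without siRNA 2 library 1 (adjusted p = 0.0622). TMEM110, current name STIMATE, is the neighbour of SFMBT1 in the gene order of GRCh38.p14. It fell by 0.82 with siRNA 2 (limma, adjusted p = 7.7e-05) and lay at 0.20 with siRNA 1 (adjusted p = 0.134), a difference of -1.02 ± 0.10 (adjusted p = 3.9e-04) that held without each library.

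The rise of replication and mitosis genes, with a median of 1.37 over 82 genes (quartiles 1.16 and 1.63), was weighed against technical causes. Scaling of the libraries is argued against by medians of 1.30 with median centring and 1.33 with quantile normalisation, and a single deviant scrambled library by a lowest median of 1.38 without each in turn. Mislabelled libraries are argued against, as SFMBT1 lay below all 3 scrambled libraries in 6 of 6 knockdown libraries. The design has 1 control set, so that a shared state of the scrambled cells, such as slower growth, cannot be told apart from an effect of the knockdown. Both stay open as hypotheses, and more cycling cells in the knockdown groups may be read from these genes only with that limit.

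Splits of the 9 libraries, which may not be separate cultures, were compared with the real grouping. For genes changed by both siRNAs on average, 2 of 100 splits were as large, the real one included (6511 genes, highest other 6777). For those changed the same way by each, 2 of 100 were as large too (4285, highest other 4370). The split with 6777 genes keeps the 3 scrambled libraries as the control and regroups the knockdown libraries along the axis within groups. It mixes the siRNAs and also gave the 4370, so the same-way count alone does not show that the reagents agree. Splits that part the scrambled libraries reached at most 313 genes and 1 gene. Chance in setting these scrambled libraries apart from the knockdown libraries is thus argued against, but a chance difference between cultures is not excluded. For siRNA 1 (5543 genes) and siRNA 2 (5944 genes), 10 splits are too few for a share under 0.05, with 1 as large and 0 genes in the highest other for either (limma, 6788 and 7093 genes at an unadjusted p under 0.05 in the real split).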
